A study of Mus musculus with 6 samples.

How the data were processed

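Total RNA of epithelial cells from the large intestine of 6 germ-free C57BL/6 mice was extracted with Trizol, biotin-labelled and hybridised to 1 Affymetrix array per mouse, per the labels' protocols. The series design text states 3 biological replicates per genotype, HDAC3FF and HDAC3ΔIEC. The deposited values are log2 signals, 1 per probe set and array, as their range of about 2 to 14 shows. Affymetrix Power Tools is named in the submitters' processing notes. Its version, the background correction, the normalization and any filter are not given in the sources used here, and signals below background are not marked. The values were used as deposited, with no further normalization in the main analysis. No 2 arrays held the same values: at most 0.00133 of the genes had equal signals on any pair of arrays.

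Of the probe sets, 21105 have 1 gene symbol in the platform's annotation, 1254 have several and 2580 have none listed. Of the 21105, 21022 were matched through the Entrez gene number to the RefSeq gene table of assembly GRCm38.p6, which changed 0 symbols, and 83 were not matched and kept their symbol. Where a gene had more than 1 probe set (882 genes), the probe set with the highest mean over the 6 arrays was used, which gave 19533 genes. Probe sets with several genes or none were left out of the gene tests.

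HDAC3ΔIEC was compared with HDAC3FF by limma 3.58.1 (lmFit and eBayes with default settings, two-sided) in R 4.3.3, with no covariate, and p-values were adjusted by Benjamini-Hochberg over the 19533 genes. A gene was called at an adjusted p under 0.05. Standard errors are limma's moderated ones, with 3.26 prior degrees of freedom. Gene lists were tested with camera at its preset correlation between genes of 0.01, adjusted over the 33 lists with at least 5 measured members, and again with an estimated correlation and with fry. Of 36 lists with 765 entries, 692 entries were measured here, 25 are only on probe sets that name several genes and 48 have no probe set among those used here. Within a list, p-values were also adjusted over the list alone. The smallest adjusted p over the lists was 0.496 with an estimated correlation and 0.0720 with fry, which asks whether the members move one way on balance. Fry's mixed test, which asks for change in either direction, passed 20 of the 33 lists.

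The groups, tests, gene lists, rule for named genes and all alternatives except the omission of replicate 3 of both groups were chosen before the data were examined. Named genes are Hdac3; the 8 largest rises and 8 largest falls among called genes whose groups do not overlap, leaving out predicted models and clone names; for each list up to 4 called members with the largest change or, if none was called, up to 2 members with the smallest p; Epcam, Vil1 and the 2 brightest members of each list of other cells; and the sex-linked genes. Other genes named were chosen after their values were seen: Sst, Gcg, Cck, Chga, Chgb, Reg3g, C1qb and C1qc in the results, and genes named only in the additional observations.

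The alternatives were a replicate block, an intensity trend or a robust prior in eBayes, array weights, quantile normalization, centring of each array on its median, filters on dim genes at the 25th percentile and at the median, the mean of all probe sets of a gene, adjustment over all probe sets, omission of each array in turn, an adjusted p under 0.10, a log2 fold change of at least 1, ordinary unmoderated statistics and, for lists, an estimated correlation, fry and ranks.

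The tests were checked on simulated data with the real genes' means and spreads, 3 arrays against 3, in 10 runs with 200 of 19533 genes changed. Of the genes changed by 0.5 on the log2 scale 25.8% were called, and of those changed by 1, 2 and 3, 77.6%, 94.8% and 99.6%. Of 192695 unchanged genes 98 were called. Camera found 30 of 30 lists shifted by 0.5 with the preset and 29 with an estimated correlation, and called 1 of 287 untouched lists; the simulated genes were independent of each other. Tables were prepared with Python 3.11.15 and figures with matplotlib 3.10.9.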

Results

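Gene expression was profiled in primary epithelial cells of the large intestine of germ-free C57BL/6 mice, which carry no microbiota. Live cells positive for the epithelial surface protein EpCAM had been isolated from 3 control mice with floxed Hdac3 alleles (HDAC3FF) and from 3 mice whose intestinal epithelial cells lack Hdac3 (HDAC3ΔIEC), and total RNA from each was hybridised to 1 Affymetrix array. HDAC3 is a histone deacetylase that acts within NCoR and SMRT corepressor complexes. The comparison asks which transcripts of these cells differ with Hdac3 in the absence of bacteria. Deposited log2 signals were used, 1 per gene and array, for 19533 genes. Median signals lay between 5.25 and 5.31 on the 6 arrays, and the highest signals between 13.40 and 13.55. With 3 arrays per group, the number of arrays limits the precision of every value below.

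Hdac3 itself, the targeted gene, read 6.96, 7.36 and 7.04 on the HDAC3FF arrays (mean 7.12 ± 0.21, SD, n = 3) and 6.58, 6.22 and 6.00 on the HDAC3ΔIEC arrays (mean 6.27 ± 0.29, SD, n = 3). All 3 HDAC3ΔIEC values lay under all 3 control values, at 55.3% of the control level on average. The log2 fold change of -0.86 ± 0.17 (SE) did not pass over all genes (limma adjusted p = 0.0937). The exact two-sided permutation test gave p = 0.1, the smallest that 3 against 3 arrays allow. The probe set can hold probes outside the deleted part of the gene, and such probes check nothing.

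The largest rise in HDAC3ΔIEC against HDAC3FF was that of Wfdc18, a member of the whey acidic protein family, which went from 5.51 ± 0.37 to 10.03 ± 0.06 (SD, n = 3 each). Rises of 8.42-fold and 8.41-fold were measured for Ppy and Insl5, which encode the peptide hormones pancreatic polypeptide and insulin-like peptide 5, and one of 8.38-fold for Ereg, which encodes the EGF receptor ligand epiregulin. Mal, a proteolipid of apical membrane sorting, fell 5.03-fold, and Mptx1, a mucosal pentraxin, fell 4.04-fold from a high control level of 11.24 ± 0.35 (SD, n = 3).

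Of the 19533 genes, 137 passed limma's test at an adjusted p under 0.05, 72 of them higher and 65 lower in HDAC3ΔIEC, and 73 of these changed by at least 1 on the log2 scale (41 higher, 32 lower). None of the 137 had overlapping groups, and over all genes the groups did not overlap for 16.2%, against 10% by chance. Among the 8 largest rises were also Pbp2, a phosphatidylethanolamine-binding protein (log2 fold change 3.96 ± 0.34, SE), Ckb, the brain-type creatine kinase (2.83 ± 0.15), the mitochondrial carrier Slc25a45 (2.71 ± 0.15) and the stearoyl-CoA desaturase Scd1 (2.51 ± 0.31). The other large falls, predicted gene models aside, were those of the carboxylesterase Ces1d (-2.05 ± 0.28), the soluble epoxide hydrolase Ephx2 (-2.03 ± 0.32), the metalloproteinase inhibitor Timp3 (-1.96 ± 0.23), the heparan sulphate proteoglycan Sdc2 (-1.86 ± 0.21), the annexin Anxa13 (-1.78 ± 0.25) and the complement gene C1qa (-1.71 ± 0.19). The limma adjusted p of these 16 genes ran from 0.000392 for Wfdc18 to 0.0481 for Ephx2.

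**Figure D1:**
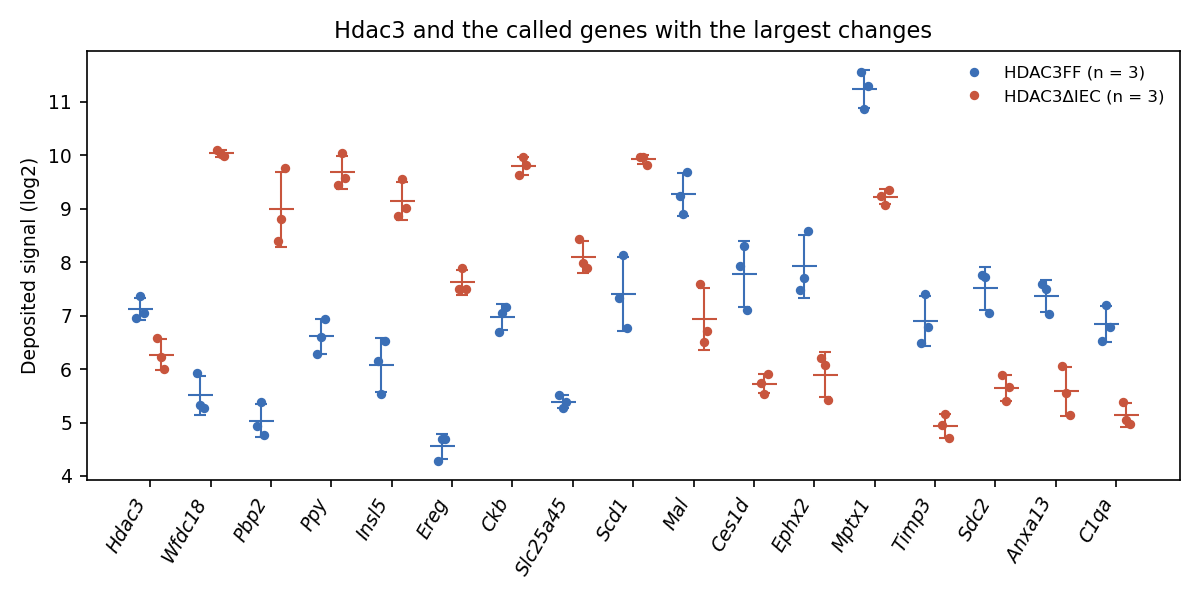
Deposited log2 signal of Hdac3 and of the 8 called genes with the largest rise and the 8 with the largest fall on each array (points), with the group mean and SD (bars, n = 3 per group). The rises and falls were taken from genes whose groups do not overlap, and the groups of Hdac3 do not overlap either. Wfdc18 reads 5.51 on average in HDAC3FF and 10.03 in HDAC3ΔIEC.

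The number of passing genes depended on the arrays used: it was 13 without HDAC3FF replicate 1, 46 without replicate 2 and 430 without replicate 3, and 46, 14 and 29 without HDAC3ΔIEC replicates 1, 2 and 3. With array weights 357 passed, with adjustment over all probe sets 90, and with ordinary unmoderated statistics 0, where 1858 genes had an unadjusted p under 0.05, against 2192 with limma. Of the 33 named genes that passed with all arrays, 7 passed without each of the 6 arrays in turn, namely Wfdc18, Ppy, Ereg, Ckb, Slc25a45, Slc9a3 and Vnn1. Every one of the 137 kept its direction, which leaving out or weighting arrays could not change, since their groups do not overlap.

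Of 20 measured enteroendocrine cell genes, 2 rose, none fell and 18 did not pass. Adjusted over the list alone, 8 were higher and 1 was lower. The 2 that rose were Insl5 (3.07 ± 0.28, SE) and Pyy (2.22 ± 0.33), the gene of peptide YY, at limma adjusted p of 0.00923 and 0.0405. Sst (2.74 ± 0.44), Gcg (1.91 ± 0.43) and Cck (1.84 ± 0.42), the genes of somatostatin, proglucagon and cholecystokinin, did not pass over all genes, nor did the granule genes Chga (0.75 ± 0.30) and Chgb (0.58 ± 0.25). The list's median log2 fold change was 0.47 (camera adjusted p = 2.82e-07), with an adjusted p = 0.496 with an estimated correlation. It was 1.06 among the members above the dim filter at the median of all genes. That filter uses the mean over both groups, so a member's own rise helps it pass.

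**Figure D2:**
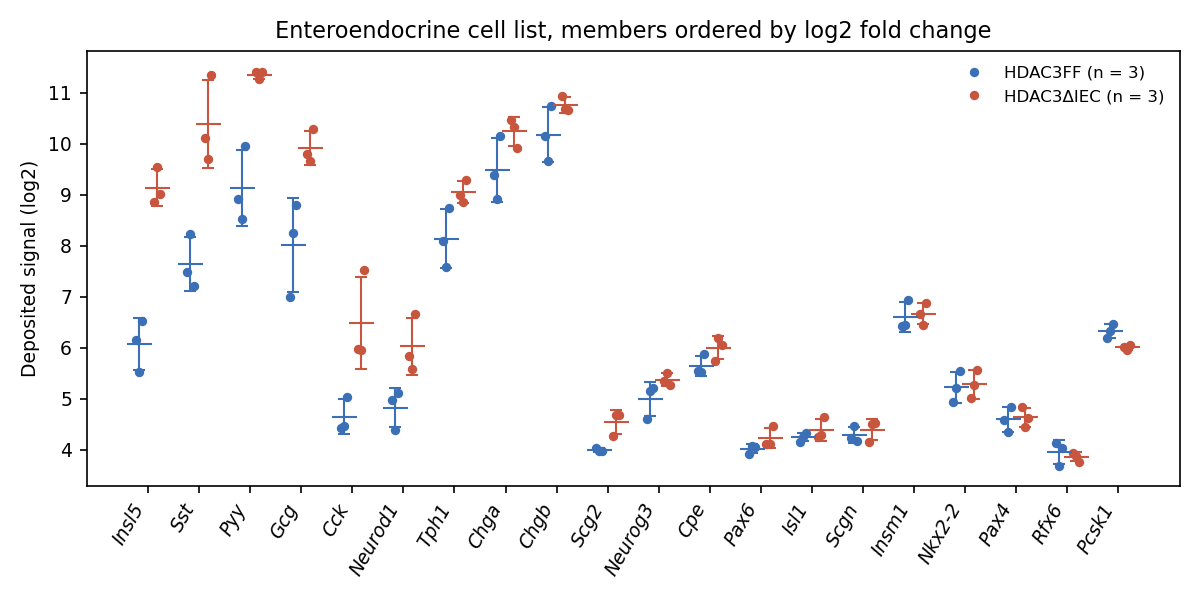
Deposited log2 signal of the 20 measured enteroendocrine cell genes on each array (points), with the group mean and SD (bars, n = 3 per group), ordered by log2 fold change. Insl5 and Pyy passed over all genes, and Chga and Chgb lie at log2 fold changes of 0.75 and 0.58.

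Of 32 measured genes of fatty acid oxidation and targets of the nuclear receptors PPAR, 5 rose, none fell and 27 did not pass, against 11 higher and none lower adjusted over the list alone. Pdk4, a kinase that restrains pyruvate oxidation, rose by 2.02 ± 0.28 (SE), the pantetheinase Vnn1 by 1.96 ± 0.11, the lipase inhibitor Angptl4 by 0.89 ± 0.08 and Cpt2, the inner membrane carnitine palmitoyltransferase, by 0.72 ± 0.09. The median log2 fold change of 0.27 passed with camera (adjusted p = 1.78e-08), with an adjusted p = 0.496 with an estimated correlation. Without HDAC3FF replicate 3 the median was 0.15, and without replicate 3 of both groups 0.14, and both passed with camera.

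Fatty acid synthesis genes showed 3 rises and no fall among 20 measured members, and 17 did not pass; adjusted over the list alone, 8 were higher and 1 lower. Scd1, the malic enzyme Me1 (2.15 ± 0.26, SE) and the acyltransferase Agpat2 (0.66 ± 0.08) rose. The list's median was 0.30 (camera adjusted p = 0.00158), with an adjusted p = 0.665 with an estimated correlation. It was 0.11 without HDAC3FF replicate 3 and 0.20 without HDAC3ΔIEC replicate 1, and passed with camera in both, and with the mean of all its probe sets Me1 had a log2 fold change of 1.38 and did not pass. Among 18 measured LXR and FXR targets and lipoprotein genes, Nr0b2, which encodes the corepressor SHP (0.72 ± 0.10), and the lysophospholipid acyltransferase Lpcat3 (0.62 ± 0.09) rose, none fell and 16 did not pass, while 8 were higher and 1 lower adjusted over the list alone. Its median was 0.25 (camera adjusted p = 0.00387), with an adjusted p = 0.692 with an estimated correlation, and it did not pass with camera on ranks.

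None of the 20 measured cholesterol synthesis genes passed, over all genes or adjusted over the list alone. Fdps and Hmgcs1 had the smallest p (0.37 ± 0.09 and 0.65 ± 0.18, SE). The list's median of 0.26 passed with camera (adjusted p = 0.00247) and had an adjusted p = 0.767 with an estimated correlation. Without HDAC3FF replicate 1 it had a median of 0.13 and passed, and without HDAC3ΔIEC replicate 2 it had a median of 0.14 and no longer passed (camera adjusted p = 0.0646, in a range from 7.88e-06 to 0.0646 with arrays left out). Of 15 measured glycolysis genes, Hk2, a hexokinase, rose (0.99 ± 0.14, SE), none fell and 14 did not pass, against 7 higher and none lower adjusted over the list alone. The glycolysis median was 0.34 (camera adjusted p = 0.000151), with an adjusted p = 0.496 with an estimated correlation.

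Oxidative phosphorylation and cell cycle genes passed as lists with no single member past the threshold, over all genes or adjusted over the list alone. The 27 measured oxidative phosphorylation genes, of which Sdhc (0.46 ± 0.15, SE) and Uqcrc1 (0.39 ± 0.16) had the smallest p, had a median of 0.18 (camera adjusted p = 0.00371, adjusted p = 0.801 with an estimated correlation). Without HDAC3FF replicate 3 their median was 0.08, and with array weights 0.14, and neither passed. The camera adjusted p was 0.574 without that array, in a range from 2.32e-06 to 0.631 with arrays left out. The 36 measured cell cycle genes, led by Aurka (0.46 ± 0.16) and Ccne1 (0.26 ± 0.10), had a median of 0.09 (camera adjusted p = 0.00387, adjusted p = 0.801 with an estimated correlation). With array weights this list did not pass either, at a median of 0.09, while its median was 0.25 without HDAC3FF replicate 2 and 0.16 without HDAC3ΔIEC replicate 1, and passed in both. Without HDAC3FF replicate 3 the median was -0.01 (camera adjusted p = 0.963), and without HDAC3ΔIEC replicate 2 it was 0.06 (camera adjusted p = 0.118, in a range from 3.53e-08 to 0.963 with arrays left out).

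Antigen presentation was the 1 list that passed in the lower direction. None of its 13 measured genes passed, over all genes or adjusted over the list alone, and 12 had negative log2 fold changes, with the smallest p for Erap1 (-0.47 ± 0.18, SE) and Tap2 (-0.29 ± 0.11). Its median was -0.15 (camera adjusted p = 0.00287), with an adjusted p = 0.496 with an estimated correlation. Its median was -0.27 without HDAC3FF replicate 2 and -0.30 with the dim filter at the median of all genes, and passed in both. With replicate 3 of both groups left out, the median was -0.13 and did not pass (camera adjusted p = 0.0565, in a range from 0.000355 to 0.0565 with arrays left out). In all, 9 of 33 tested lists passed with camera's preset correlation, 8 higher and 1 lower, and 0 passed with an estimated correlation or with fry, where 1 and 8 had an unadjusted p under 0.05.

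**Figure D3:**
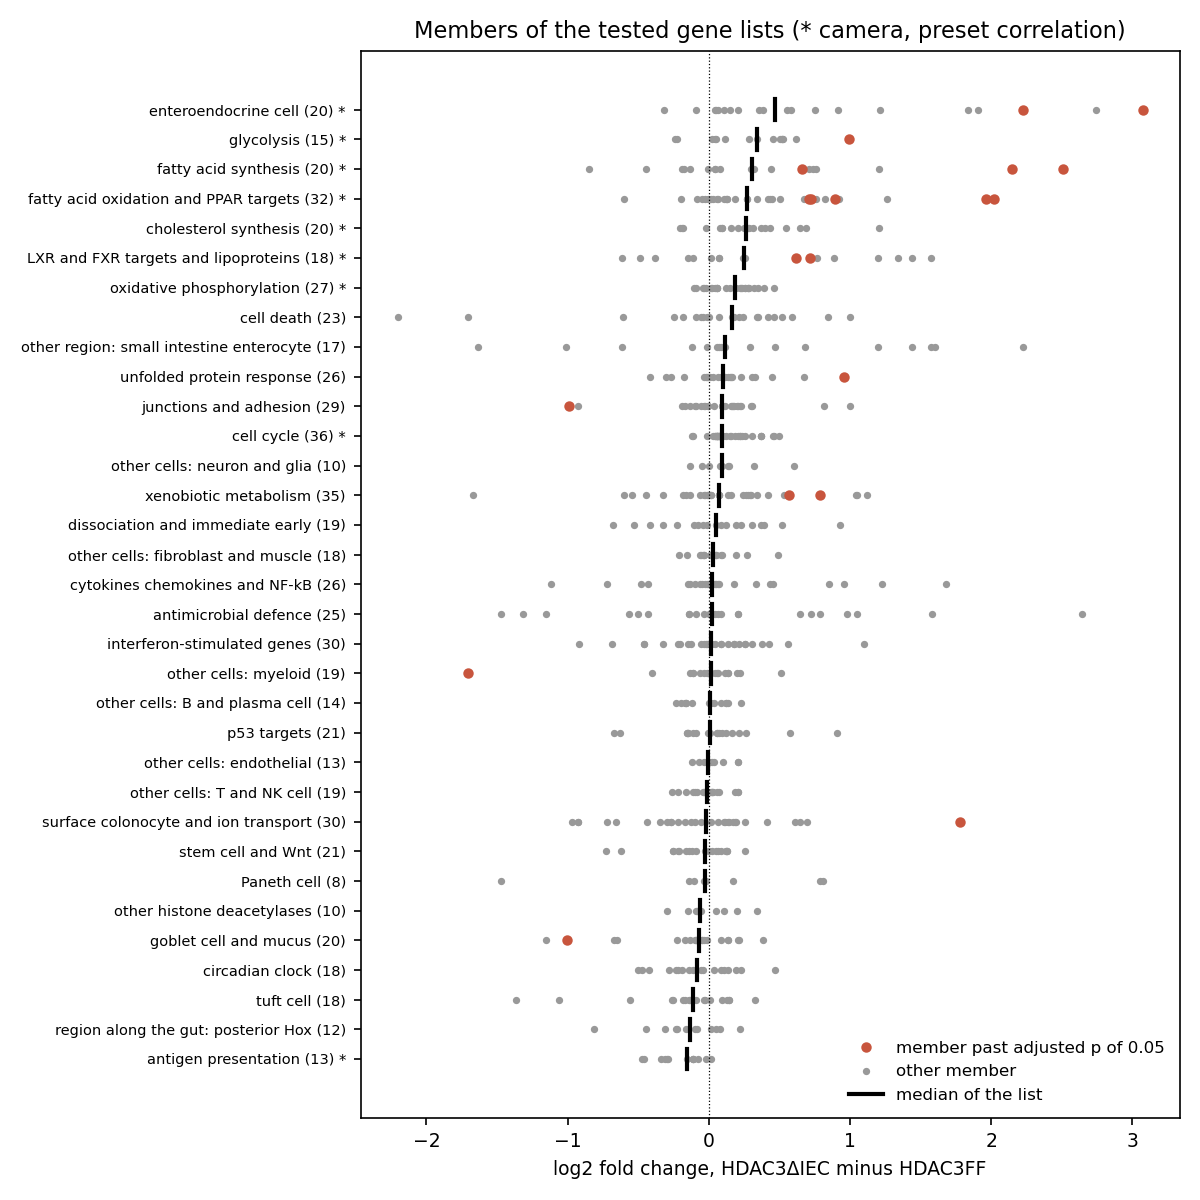
Log2 fold change (HDAC3ΔIEC minus HDAC3FF) of each measured member of the 33 tested gene lists (points), with the median of each list (black bar) and the number of members in parentheses. Asterisks mark the 9 lists past camera's test with the preset correlation, with medians from -0.15 for antigen presentation to 0.47 for enteroendocrine cells.

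Secretory lineage and defence genes gave values in both directions, with 1 call over all genes. None of 25 measured antimicrobial defence genes passed over all genes, while 2 were higher and 4 lower adjusted over the list alone. Retnlb, which encodes the goblet cell protein RELMβ, had a log2 fold change of -1.15 ± 0.19 (SE, limma adjusted p = 0.0568), and the angiogenin Ang4 one of -1.47 ± 0.34 (limma adjusted p = 0.127). The lectin Reg3g read 2.65 ± 0.67 higher, which also did not pass (limma adjusted p = 0.161). The list's median of 0.02 and mean of 0.13 were positive, whereas camera's direction was down (adjusted p = 0.926). Of 20 measured goblet cell and mucus genes, the chemokine gene Ccl9 fell (-1.01 ± 0.12), none rose and 19 did not pass, with 2 lower and none higher adjusted over the list alone (median -0.07, camera adjusted p = 0.0617). None of the 8 measured Paneth cell genes passed, and 1 was higher and 1 lower adjusted over the list alone (median -0.03, camera adjusted p = 0.926). Lyz1 (0.79 ± 0.17) had the smallest p, at mean signals of 3.97 in HDAC3FF and 4.76 in HDAC3ΔIEC. The median of the 8 genes' mean signals was 4.24, under the median of every array, so their values say little about Paneth cells. None of the 18 tuft cell genes passed, with Nrep at -1.06 ± 0.24 and Gng13 at -1.36 ± 0.41 (median -0.11, camera adjusted p = 0.186). None of the 21 stem cell and Wnt genes passed, with Lgr5 at -0.73 ± 0.23 and Myb at -0.62 ± 0.20 (median -0.03, camera adjusted p = 0.320). Neither of these last lists had a passing member adjusted over the list alone. As lists, the goblet cell genes passed without HDAC3FF replicate 1 or 2 or HDAC3ΔIEC replicate 1, with medians of -0.09, -0.15 and -0.06 (camera adjusted p from 0.00559 to 0.998 with arrays left out), and with quantile normalization or an intensity trend. The tuft cell genes passed without HDAC3FF replicate 2 or HDAC3ΔIEC replicate 1, with medians of -0.20 and -0.29 (0.000825 to 0.876 with arrays left out).

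Slc9a3, which encodes the sodium-proton exchanger NHE3, rose by 1.78 ± 0.09 (SE), the only 1 of 30 measured surface colonocyte and ion transport genes to pass over all genes. None of these fell and 29 did not pass; adjusted over the list alone, 2 were higher and 2 lower (median -0.02, camera adjusted p = 0.913). Among 29 measured junction and adhesion genes, the claudin Cldn15 fell (-0.99 ± 0.12), none rose and 28 did not pass, against 2 lower and none higher adjusted over the list alone (median 0.10, camera adjusted p = 0.709). Of 35 measured xenobiotic metabolism genes, Cyp2d26 (0.79 ± 0.12) and the microsomal epoxide hydrolase Ephx1 (0.57 ± 0.08) rose, none fell and 33 did not pass, while 10 were higher and 3 lower adjusted over the list alone (median 0.07, camera adjusted p = 0.0617). Asns, asparagine synthetase, rose (0.96 ± 0.14) as 1 of 26 measured genes of the unfolded protein response, none fell and 25 did not pass, with 2 higher and none lower adjusted over the list alone (median 0.10, camera adjusted p = 0.0750). Without HDAC3FF replicate 3 or HDAC3ΔIEC replicate 3 the junction list passed, with medians of 0.18 and 0.15, and so did the unfolded protein response list, with medians of 0.14 and 0.12, and without HDAC3FF replicate 1 the xenobiotic list passed, with a median of 0.08. With arrays left out their camera adjusted p ran from 2.71e-05 to 0.986, 0.000626 to 0.311 and 0.0283 to 0.209. With all arrays kept, array weights also let the junction and unfolded protein response lists pass (camera adjusted p = 0.0309 and 0.00884). An intensity trend let the xenobiotic list pass (camera adjusted p = 0.0493).

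Of the lists of cell death, cytokines, p53 targets, interferon response, circadian clock and other histone deacetylases, no member passed over all genes. Adjusted over the list alone, 3 of 23 cell death genes were higher and 3 lower, with Bcl2 at -0.61 ± 0.11 (SE) and Gsdmc2 at -2.20 ± 0.45 (median 0.17, camera adjusted p = 0.420). On the same basis, 3 of 26 cytokine, chemokine and NF-kB genes were higher and 1 lower, with Tnf at 0.96 ± 0.17 and Il1rn at 1.23 ± 0.25 (median 0.03, camera adjusted p = 0.420). Of 21 p53 targets, 1 was higher and 1 lower adjusted over the list alone, with Plk2 at 0.91 ± 0.18 and Fas at -0.67 ± 0.15; the median of 0.01 and mean of 0.02 were positive, whereas camera's direction was down (adjusted p = 0.926). Of 30 interferon-stimulated genes, 1 was higher adjusted over the list alone, with Bst2 at 0.56 ± 0.11 and Ifit2 at 1.10 ± 0.31 (median 0.02, camera adjusted p = 0.926). Without HDAC3FF replicate 3 the interferon list had a median of 0.16 and passed (camera adjusted p = 0.0484, in a range from 0.000267 to 0.781 with arrays left out). Without replicate 3 of both groups the cytokine list passed at a median of 0.08 (camera adjusted p = 0.0431, in a range up to 0.815). None of 18 circadian clock genes passed adjusted over the list alone, with Usp2 at -0.48 ± 0.12 and Bhlhe40 at 0.47 ± 0.12 (median -0.08, camera adjusted p = 0.380), and none of 10 other histone deacetylase genes, with Hdac9 at -0.30 ± 0.09 and Hdac1 at 0.34 ± 0.13 (median -0.07, camera adjusted p = 0.896). Of the HDAC3 corepressor complex, 4 genes were measured, too few for a list test: Tbl1x, which encodes a subunit of that complex, rose (0.65 ± 0.09), and adjusted over the list alone 2 were higher and 1, Hdac3, lower.

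Markers of the sorted population were close in both groups, Epcam at -0.06 ± 0.10 (SE) and Vil1 at 0.18 ± 0.13. Of 19 measured myeloid genes, C1qa fell and 18 did not pass, none rose, and 1 was lower adjusted over the list alone. Cd14, with C1qa the brightest of these, had a log2 fold change of -0.40 ± 0.16, and the partner genes C1qb and C1qc had 0.07 ± 0.10 and -0.11 ± 0.11 at mean signals of 4.46 to 4.76. The myeloid median of 0.01 was positive, whereas its mean of -0.06 and camera's direction were negative (adjusted p = 0.926). No member passed over all genes among 19 T and NK cell genes (median -0.01, camera adjusted p = 0.854; Ccl5 -0.26 ± 0.15, Cd7 0.02 ± 0.09), 14 B and plasma cell genes (0.786; Derl3 0.14 ± 0.12, Ighm -0.12 ± 0.11), 18 fibroblast and muscle genes (median 0.03, 0.786; Tagln 0.27 ± 0.15, Vim 0.49 ± 0.19), 13 endothelial genes (0.926; Lyve1 0.21 ± 0.15, Cldn5 0.10 ± 0.09) and 10 neuron and glia genes (median 0.09, 0.117; Ret 0.60 ± 0.13, Snap25 0.32 ± 0.17). Adjusted over the list alone, 1 neuron and glia gene was higher and none passed in the other 4. The B and plasma cell median was 0.01 against a mean of -0.02 and camera's direction down, and the endothelial median was -0.003 against a mean of 0.02 and camera's direction up. Under quantile normalization or median centring both medians took either sign, from -0.01 to 0.02 and from -0.004 to 0.008. Of the red blood cell list 2 genes were measured and neither passed, over all genes or adjusted over the list alone (Alas2 -0.11 ± 0.10, Slc4a1 0.09 ± 0.09).

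Of the lists of small intestine enterocyte and posterior Hox genes, which bear on position along the gut, no member passed over all genes. Of 17 small intestine enterocyte genes, 6 were higher and 1 lower adjusted over the list alone (median 0.11, camera adjusted p = 0.0750): Mttp, which loads lipid onto lipoproteins, had a log2 fold change of 1.58 ± 0.31 (SE), and Slc10a2, the ileal bile acid transporter, one of -1.63 ± 0.31. None of 12 posterior Hox genes passed adjusted over the list alone, with Hoxd10 at -0.81 ± 0.21 and Hoxb9 at -0.23 ± 0.10 (median -0.13, camera adjusted p = 0.121). The small intestine list passed without HDAC3FF replicate 3 (median 0.33), without HDAC3ΔIEC replicate 3 (0.19) and without both (0.37), with camera adjusted p from 2.71e-05 to 0.517 with arrays left out, and also with array weights or an intensity trend. The posterior Hox list passed without HDAC3FF replicate 1, at a median of -0.20 (0.0162 to 0.517 with arrays left out). Of 19 dissociation and immediate early genes 1 was higher adjusted over the list alone, with Ier3 at 0.93 ± 0.16 and Jund at 0.39 ± 0.15 (median 0.05, camera adjusted p = 0.587). That median was 0.27 without HDAC3FF replicate 3 and passed, and was -0.25 without HDAC3FF replicate 2 (camera adjusted p from 0.000483 to 0.729 with arrays left out).

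The arrays differed within their groups as well. Male-specific transcripts (Uty, Kdm5d and Eif2s3y) read 6.83 to 8.39 on HDAC3ΔIEC replicate 3 and 3.07 to 3.67 on the other 5 arrays, and Xist, the RNA of the inactive X chromosome, read 4.63 on that array and 9.84 to 10.62 on the others. None of these 4 sex-linked genes passed, over all genes or adjusted over the list alone, and 3 of the 137 called genes lie on the X chromosome and 0 on the Y. The first principal component, 40.1% of the variance, separated the genotypes, and on the second, 26.8%, HDAC3FF replicate 3 lay at -28.0 with the other 5 arrays between -6.58 and 15.2. With replicate 3 of both groups left out, a setting chosen after the data were seen, 744 genes passed, 390 higher and 354 lower, of which 133 were among the 137.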

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

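All tests of explanations in this part were chosen after the results were seen. Probe sets outside the gene comparison also gave signals above the control level. With p-values adjusted over all probe sets, 101 passed limma's test, 10 of which name no gene or several. Of the 7 passing probe sets with no listed gene, 6 were higher in HDAC3ΔIEC, by 3.37, 3.18, 1.75, 1.63, 1.38 and 0.90 on the log2 scale, and 1 was lower (-1.27). Of the 3 that name several genes, 2 were higher, by 2.62 and 0.88, and 1 was lower (-1.56). No gene is assigned to them here.

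Other splits of the arrays bear on both counts of calls. Of the 10 splits of the 6 arrays into 3 and 3, 1, the genotype split, gave as many as 137 genes, and the highest of the others gave 0 by limma, although up to 2149 genes had an unadjusted p under 0.05 there, against 2192 in the genotype split. For gene lists, 4 of the 10 splits gave at least the 9 lists of the genotype split, and the highest other split gave 14. That split sets HDAC3FF replicates 1 and 2 with HDAC3ΔIEC replicate 3 against the rest. With 10 splits no share under 0.05 can be reached. The other splits also mix the genotypes, so a genotype difference adds to their spread and holds down their number of passing genes.

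The third replicate of each group stood apart from the rest of its group. The sex of the animal behind HDAC3ΔIEC replicate 3 does not account for all calls. Among the 5 arrays without male-specific transcripts, 29 genes passed for genotype by limma. Any other split into 3 and 2 gave 0, but those splits mix the genotypes. A genotype difference then adds to their spread and holds down their calls, so the 0 lends no further weight. At an unadjusted p under 0.05 the genotype split gave 2008 genes, fewer than the 2784 of HDAC3FF replicate 3 with HDAC3ΔIEC replicates 1 and 2 against the rest. Quantile normalization left 0.979 of the gap of HDAC3FF replicate 3 to the nearest array on the second principal component. The deposited signals already had close distributions, with array medians of 5.25 to 5.31, so this step could change little. The gap is therefore not one of overall distribution in the deposited values, and other technical causes were not tested by it. A stronger immediate early response of the cells of HDAC3FF replicate 3 in handling may contribute. On that array 16 of 19 dissociation and immediate early genes were higher than the mean of the other HDAC3FF arrays, by a median of 0.64. That lay at percentile 100 of 10000 random lists matched on signal, whose genes were drawn singly. Genes of 1 response can move together, so this percentile overstates the evidence, and no other list was tried on that array. Whether sex or handling shifts single genes stays open, as each is seen on 1 array.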

How the results depend on the processing

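The omission of replicate 3 of both groups was the only setting below chosen after the data were seen. All 137 genes past the threshold (72 higher, 65 lower) kept their direction under every setting that refitted the genes, as did 136 of 136 and 123 of 123 of those still tested under the dim filters. As their groups do not overlap, only quantile normalization, median centring and the mean of probe sets could have turned a direction. Leaving out 1 array at a time, which leaves fewer samples, gave 13 to 430 genes, 11 to 196 of them higher and 2 to 234 lower, with the fewest without HDAC3FF replicate 1 and the most without HDAC3FF replicate 3. The cause of that spread was not tested. Without replicate 3 of both groups 744 genes passed (390 higher, 354 lower), and with array weights 357 (171 higher, 186 lower), and the cause was not tested. Adjustment over all probe sets, a larger number of tests, gave 90, with 50 higher and 40 lower, and the dim filter at the median, with fewer genes tested, gave 99 lower. An adjusted p under 0.10 gave 321 (141 higher, 180 lower), and a log2 fold change of at least 1 gave 73 (41 higher, 32 lower), both by construction. Ordinary unmoderated statistics, which borrow no spread across genes, gave 0, with 0 higher and 0 lower, and 1858 genes at an unadjusted p under 0.05. The intensity trend, robust prior, quantile normalization, median centring, dim filter at the 25th percentile and mean of probe sets gave 123 to 178 genes. The Hdac3 log2 fold change stayed between -1.01 and -0.72, with limma adjusted p from 0.0599 to 0.324. Of 33 gene lists, 9 passed with camera, 7 to 12 without 1 array, 0 with an estimated correlation (1 at an unadjusted p under 0.05) and 0 with fry (8 at an unadjusted p under 0.05); the cause was not tested. No called gene or list turned past the threshold in the other direction; the cell cycle median was -0.01 without HDAC3FF replicate 3 and did not pass there. The robust prior and the adjustment over all probe sets do not enter camera and were not run for lists, and a pseudocount does not apply to log2 values. Signals below background are not marked in the deposited values, which limits what can be said of dim genes.

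The replicate numbers are shared between the groups, and the values gave no sign that they pair the arrays. The deviations of same-numbered arrays from their group means correlated across genes at -0.0242, -0.0651 and -0.198, all under 0.1, and not every array correlated best with its own number. With 3 arrays per group, of which the third stood apart, these correlations cannot exclude a shared origin or handling of same-numbered arrays. With the replicate number as a block, 12 genes passed (10 higher, 2 lower), 11 of them among the 137, and the block leaves fewer degrees of freedom. Of 33 gene lists 11 passed with the block, 9 of them those of the main analysis. The others were the tuft cell and small intestine enterocyte lists (camera adjusted p = 0.0326 and 0.0261).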

Other observations

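The genes and tests in this part were chosen after their values were seen. Enzymes that add sugars or sulphate to glycans passed in both directions. The sialyltransferase genes St3gal5 and St6gal1 fell (-1.50 ± 0.22 and -1.21 ± 0.19, SE), as did the sulphotransferase genes Chst4 (-0.98 ± 0.12) and Gal3st2c (-1.31 ± 0.18), whereas the sialyltransferase gene St3gal4 (1.27 ± 0.19) and Galnt3 (0.74 ± 0.09), which starts mucin-type O-glycans, rose. The transmembrane mucin gene Muc4 rose by 1.61 ± 0.21. Gch1, the first enzyme of tetrahydrobiopterin synthesis, and Gchfr, its regulatory protein, rose together (1.78 ± 0.22 and 1.46 ± 0.17). In retinoid metabolism the dehydrogenase Rdh9 (1.62 ± 0.18) and the binding protein Rbp7 (1.53 ± 0.12) rose and Lrat, which esterifies retinol, fell (-0.87 ± 0.13). All of these had limma adjusted p between 0.00458 and 0.0486, and no enrichment was tested.

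Among other single genes that passed, Fgfr2 fell by 1.68 ± 0.22 (SE), Kit by 1.25 ± 0.19 and the Notch ligand gene Dll1 by 0.72 ± 0.07 on the log2 scale, and the nuclear receptor gene Hnf4g fell by 1.49 ± 0.20. The monoacylglycerol lipase Mgll rose by 2.45 ± 0.11, Gclc, the catalytic subunit of the first enzyme of glutathione synthesis, by 0.92 ± 0.13, and the chemokine gene Cxcl13 fell by 1.41 ± 0.18. Their limma adjusted p lay between 0.000645 and 0.0452, and they stand for no group.

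Over Insl5, Pyy, Sst, Gcg and Cck the mean log2 fold change was 2.36 ± 0.31 (SE), against 0.39 ± 0.22 over the 6 other members with at least the mean signal of Cck, the dimmest of the 5 (Chga, Chgb, Cpe, Insm1, Pcsk1 and Tph1), which leaves out the slightly dimmer Neurod1 at 1.21 ± 0.30. The difference was 1.96 (95% interval 1.27 to 2.66), or 1.69 (0.57 to 2.81) against Chga and Chgb, the 2 at or above the hormone genes' median signal. The 5 hormone genes were grouped after their rises were seen. These intervals partly restate that choice and decide nothing about the share of enteroendocrine cells. Of the 66 pairs among all 12 members above the median signal, 32 differed in their change by limma, adjusted over the pairs. Of these, 28 were a hormone gene with another member and 0 were 2 hormone genes. The cut used the mean over both groups, so a member's own rise helped it past. If each signal comes from enteroendocrine cells alone, these counts go against an equal rise of all members, as a larger share of enteroendocrine cells of all kinds alike would give. That condition was not tested. Cpe, Insm1 and Pcsk1 had mean signals of 5.82, 6.63 and 6.16, where background can hide part of a rise. Chga and Chgb, at 9.87 and 10.47, also differed from Insl5, Pyy and Sst. The counts are less certain than limma's p-values make them, since the pairs share genes and are not independent. The division between hormone genes and other members is not complete: Cck and Gcg did not differ past the threshold from Neurod1, Chga or Tph1, nor Pyy from Neurod1. A hypothesis that stays open is a change in the kinds of enteroendocrine cells or in their hormone transcription. A more distal origin of the HDAC3ΔIEC cells, which might bring more Insl5, cannot be told apart from these, because the mean of the posterior Hox genes was -0.17 with an interval of -0.47 to 0.14.

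Retnlb, Ang4, Wfdc2 and Reg4, the 4 antimicrobial defence genes lower adjusted over the list alone, had a mean log2 fold change of -1.09 ± 0.27 (SE), while each missed the threshold over all genes. The low values were not confined to HDAC3ΔIEC replicate 3: on both other HDAC3ΔIEC arrays each of the 4 lay under all its control values. Without replicate 3 all 4 were still lower adjusted over the list alone, with a mean of -0.91. The 4 were chosen for being lower over all 6 arrays, which favours both outcomes. Neither is therefore separate evidence, and the mean is no separate measure of size. A smaller share of goblet cells might also lower these 4 genes and cannot be told apart from a change in the genes themselves. The mean of 12 other goblet cell genes was -0.17 (95% interval -0.63 to 0.30), with 6 near the top of the signal range and Retnlb and Zg16, which are also on the antimicrobial list, left out, and Retnlb and Reg4 themselves lie near the top of that range.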
